A study of Mus musculus with 18 samples.

How the data were processed

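Liver RNA of 18 mouse libraries was measured by the authors with a targeted panel (Ion AmpliSeq mouse transcriptome) that reads 1 amplicon per gene, per the labels. The mice carried floxed Yap alleles and received, at 8 weeks of age, an adeno-associated virus with a hepatocyte promoter that delivered Cre (knockout, dose 0.5), YAP with EGFP (overexpression, dose 2) or GFP alone (control, dose 2). The doses are in the same unit of genome copies per mouse, so the dose of virus differed between knockout and control. After 2 weeks they were moved to liquid diet, with 5 days of acclimation and 4 weeks of ethanol or control diet, and a final gavage of ethanol (5 g/kg, 33% v/v) or of maltose-dextrin 9 hours before death. The labels number the replicates 1 to 3 in each of the 6 groups without stating that each library is a separate animal, so the p-values measure the spread between libraries. They do not state the sex of the mice, and neither the position of the Yap1 amplicon relative to the floxed exon nor the species of the YAP transgene is given.

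The deposited series table holds CPM (reads scaled to a common library total) for 23930 genes in 18 columns. Each deposited value was a whole number of reads within 0.02 reads once multiplied by the library total (100.0% of values in each library), so that whole reads were recovered exactly; 1 read equals 0.172 to 0.214 CPM. The per-library files hold log2(RPM + 1) values, per the file headers, made by the authors with the vendor's program ampliSeqRNA 5.10.1.2. These log2 values equal log2(CPM + 1) of the deposited table with a largest difference of 2.0e-06. The deposited CPM are scaled to the library total alone. The aligner and genome build are not given in the sources used here, so no coordinates are printed. Gene symbols are those of the panel; listed symbols of newer use were matched through their older forms, such as Cyr61 for Ccn1 and Ctgf for Ccn2. No column was left out, and raw reads were not used here.

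Genes with at least 1 CPM in at least 3 libraries were kept (11720; 4850 of the others had no read in any library). One linear model with a mean for each of the 6 groups was fitted to log2(CPM + 1) over all 18 libraries with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3. The 9 contrasts were the response to ethanol in each genotype, knockout and overexpression against control on each diet, and the 2 interactions of ethanol with genotype. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and an adjusted p under 0.05 was called. Of the gene lists fixed for alcohol-fed liver, YAP and the unfolded protein response, 30 with at least 3 kept members were tested with camera of limma (preset correlation 0.01, each list against all other genes, Benjamini-Hochberg over the lists of a contrast). Camera with an estimated correlation kept 1 call, that of acute phase genes in the ethanol response of overexpressing mice, and 0 in each of the other 8 contrasts, where the preset correlation gave 3 to 10. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The lists are members known from other work and share the libraries' own hepatocyte background, since a marker of one cell type can be transcribed in another.

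Named genes follow a rule. In each comparison of 2 groups they are the 6 largest rises and the 6 largest falls among called genes whose 3 libraries of one group all lie on one side of those of the other and whose mean is at least 5 CPM, and the 2 to 4 members with the smallest adjusted p of each of the 8 lists with the most called members. Some genes that meet the rule are not reported here, though they stay in every fit, count and list. Yap1, Cyr61, Ctgf, Ankrd1, Atf6, Hspa5 and Ddit3 are given throughout. The design, the lists, this rule and the alternatives were set before the data were examined, except where stated. Members of lists outside the rule (Srebf1 in the ethanol response of control mice, and Cd5l, Clec4f and Marco in ethanol-fed knockout mice) were chosen after their values were seen.

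Alternatives were the filter (none, or 10 CPM in 3 libraries, which keeps 7736 genes), pseudocounts of 0.1 and 10, TMM factors, quantile normalization, array weights, a replicate block, a block for the barcode range, a fit to the libraries compared alone, edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads, and leaving out each library in turn. A term for the sex chromosome genes (Xist above Ddx3y or not) and comparisons matched on them were added after the data had been seen. The pipeline was tested on simulated data of 11532 genes built from these libraries, with known changes in a small share of the genes. There limma recovered 96% of 4-fold and 40% of 2-fold changes with 12 false calls among the unchanged genes, and edgeR 98% and 44% with 8. The changed genes had a mean of at least 5 CPM, and genes were drawn independently, without a group of mixed sex or other structure between libraries. Recovery for lower genes and false calls under such structure were thus not tested. Camera called both shifted lists and 1 list that was not shifted. The simulated lists were random genes without correlation between them, so they do not test camera on correlated lists. Changes of 2-fold and below are thus often missed with 3 libraries in each group. Reads carry no molecular identifiers, so depth limits cover counting error alone.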

Results

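Gene expression was measured in the liver of mice with floxed Yap alleles. Yap was left in place with a GFP virus (control) or deleted in hepatocytes (knockout), or YAP was expressed from a virus in hepatocytes (overexpression). Each of the 3 genotypes was fed ethanol or a control liquid diet matched to it (pair-fed), with 3 libraries in each of the 6 groups and 18 libraries in all. YAP is a transcriptional coactivator of the Hippo pathway, and the title of the series names endoplasmic reticulum (ER) stress and the transcription factor ATF6 as its subject. The libraries came from a targeted panel with 1 amplicon per gene, and 23930 genes were listed. A library held 4.68 to 5.81 M reads (median 5.47 M), and 54.2 to 57.7% of the listed genes had at least 1 read. The 10 most abundant genes took 12.6 to 18.1% of the reads, and Alb was the most abundant gene in each library. Levels are given in CPM, reads of a gene scaled to a common library total, as mean ± SD of 3 libraries (n = 3). Changes are log2 fold changes ± SE from the limma fit to log2(CPM + 1), a scale that understates changes of genes near or below 1 CPM. A count of 3 reads, taken as the limit that 0 reads allow, came to 0.517 to 0.641 CPM, and this limit covers counting error alone.

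Yap1 RNA followed the genotype labels in 17 of the 18 libraries. It stood at 55.4 ± 4.8 CPM in pair-fed control, 62.4 ± 4.25 CPM in ethanol-fed control, 8.50 ± 5.82 CPM in pair-fed knockout, 4.39 ± 0.925 CPM in ethanol-fed knockout, 142 ± 79.0 CPM in pair-fed overexpression and 122 ± 19.5 CPM in ethanol-fed overexpression libraries. Pair-fed overexpression replicate 1 had 57.6 CPM of Yap1, within the range of the pair-fed controls (51.5 to 60.7 CPM), while the other 2 libraries of its group had 155 and 214 CPM. The same library had 15.7 CPM of Cyr61 and 37.5 CPM of Ctgf, both targets of YAP, against 7.48 to 8.93 CPM and 15.1 to 27.5 CPM in the pair-fed controls. The genes of the sex chromosomes divided the libraries in another way than the labels, which do not give the sex of the mice. Xist, transcribed from the inactive X chromosome, stood at 348 to 423 CPM in pair-fed control replicates 2 and 3 and in the 3 pair-fed knockout libraries, and at 0 to 2.75 CPM in the other 13 libraries. The Y-linked gene Ddx3y stood at 54.0 to 128.8 CPM in those 13 libraries, at 3.47 CPM in pair-fed control replicate 2 and at 0 in the other 4 libraries with Xist. Ethanol-fed knockout, ethanol-fed control and both overexpression groups held libraries with Y-linked reads alone, so comparisons within these 4 groups were matched on the sex chromosome genes. Comparisons with the pair-fed control or pair-fed knockout group were not, or not fully. The p-values of the matched comparisons still take their spread from all 18 libraries, the mixed pair-fed controls among them. Low Yap1 in the 3 pair-fed knockout libraries (4.18 to 15.1 CPM) runs the way their labels say. Cyp2b10, chosen after its values were seen, ran the way the diet labels say in all 18 libraries, at 13.9 to 93.3 CPM in the pair-fed and 193 to 1171 CPM in the ethanol-fed ones. By Xist and Ddx3y, pair-fed control replicates 2 and 3 and the 3 pair-fed knockout libraries have the pattern of female mice. The labels give no sex to compare this with.

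**Figure D1:**
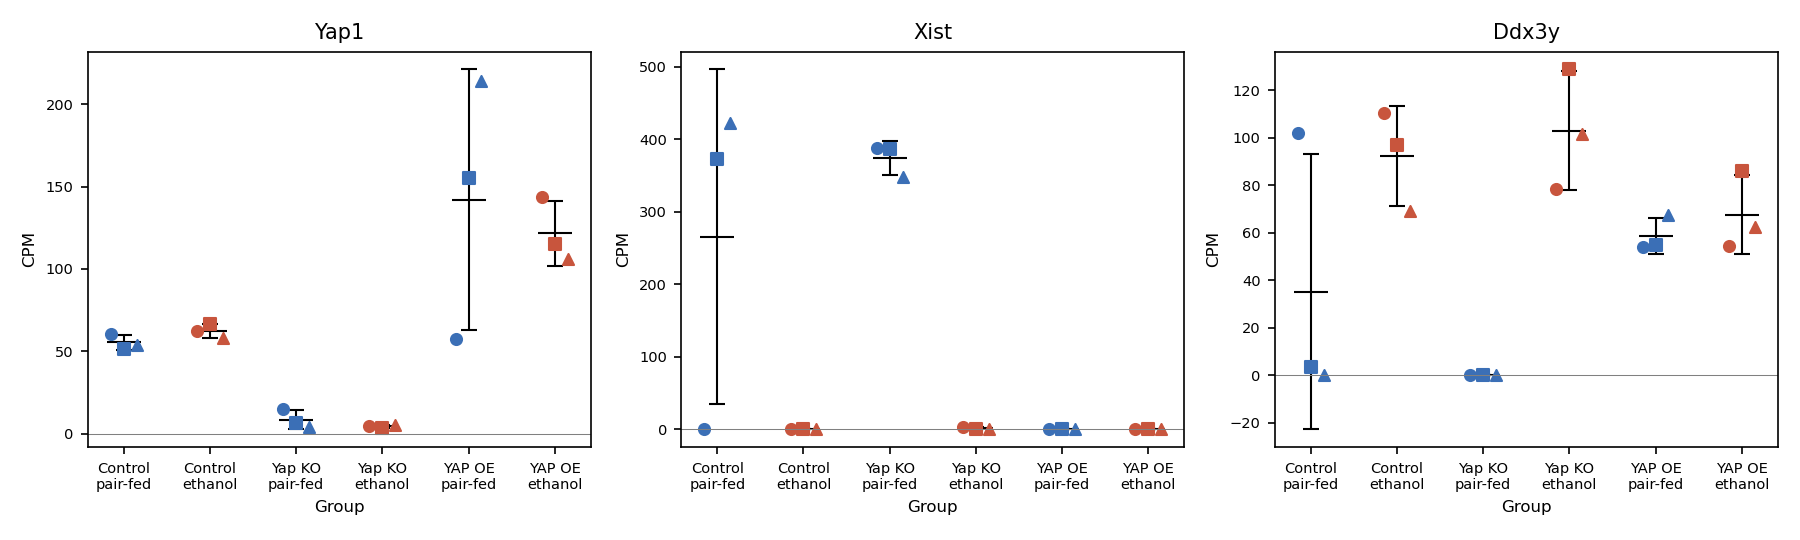
Levels of Yap1, Xist and Ddx3y in CPM (y axis) in the 6 groups (x axis), with 1 point per library (circle, square and triangle for replicates 1, 2 and 3; blue for pair-fed, red for ethanol-fed) and bars for the mean ± SD of 3 libraries. Pair-fed overexpression replicate 1 lies at 57.6 CPM of Yap1 among the controls, and Xist is at 348 CPM or above only in pair-fed control replicates 2 and 3 and in pair-fed knockout mice.

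The first comparison asked how 4 weeks of ethanol with a final gavage changed the liver of control mice. Lcn2, which encodes the iron-binding acute phase protein lipocalin 2, rose from 13.1 ± 1.28 to 430 ± 286 CPM (4.57 ± 0.86, adjusted p = 0.00934). Cyp2b10, an enzyme of drug metabolism induced through the receptor CAR, rose from 52.5 ± 35.5 to 715 ± 492 CPM (3.59 ± 0.48, adjusted p = 0.000798). The metal-binding protein gene Mt1 rose from 440 ± 461 to 5440 ± 1530 CPM (4.21 ± 0.77) and the phosphate transporter gene Slc34a2 from 0.479 ± 0.261 to 23.5 ± 8.66 CPM (3.99 ± 0.50). The potassium channel gene Kcnk5 fell from 147 ± 38.6 to 21.6 ± 8.96 CPM (-2.76 ± 0.30, adjusted p = 0.000102). Among the largest falls were also A1bg (-4.22), Hsd3b2 (-2.68), Nrep (-2.59) and Etnppl (-2.53). A1bg stood at 71.4 ± 91.9 CPM in the pair-fed controls, a group of mixed sex chromosome genes. In a fit to libraries with Y-linked reads of control and overexpressing mice it was 0.15 ± 0.51 (limma adjusted p = 0.916). Hsd3b2, Nrep and Etnppl passed there with the same sign. That fit has a common ethanol term for both genotypes, and most of its pair-fed libraries are from overexpressing mice, so it mixes genotype with sex. In control mice alone, with 1 pair-fed control library left after matching on the sex chromosome genes, A1bg was -1.86. Of the 11720 genes tested, limma called 120 higher and 196 lower with ethanol at an adjusted p under 0.05. An unadjusted p under 0.05 was reached by 2120 genes, where 586 would be expected by chance. With TMM factors the balance turned to 168 higher and 122 lower. Genes named as largest rises and falls were chosen with the 3 libraries of one group all above or below those of the other. Chance gives this for 10% of genes, but here it was fixed by the choice and adds no support.

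By fixed gene lists, the acute phase response rose with ethanol in control mice (median 0.84, 16 of 21 members positive, camera adjusted p = 2.75e-07, adjusted p = 0.422 with an estimated correlation). In that list 3 members rose over all genes (Lcn2, Steap4 1.26 ± 0.27 and Orm3 2.60 ± 0.59), and 11 adjusted over the list alone. Targets of the PERK-ATF4 branch of the stress response were higher as a list (median 0.65, adjusted p = 0.000113, and 0.424 as the adjusted p with an estimated correlation), with 2 of 19 members past the threshold over all genes and 3 adjusted over the list alone. Past the threshold over all genes were the stress hormone genes Gdf15 (3.04 ± 0.60) and Fgf21 (2.95 ± 0.78). A fit to libraries with Y-linked reads of control and overexpressing mice gave 0.78 ± 0.67 and 1.39 ± 0.56 for them (limma adjusted p = 0.587 and 0.2). In control mice alone, with libraries matched on the sex chromosome genes, they were 3.09 and 3.31. The lower values of the joint fit, whose pair-fed libraries are mostly overexpressing, can thus not be assigned to sex. The list of NRF2 targets and glutathione genes was higher (median 0.37, adjusted p = 0.000113, adjusted p = 0.422 with an estimated correlation), with Mt1 and the heme-degrading enzyme gene Hmox1 (33.3 ± 7.92 CPM to 96.2, 183 and 350 CPM, 2.45 ± 0.40) past the threshold among 15 members, and 6 higher and 1 lower adjusted over the list alone. In the fit to libraries with Y-linked reads Mt1 was 3.45 ± 0.3 and passed, and Hmox1 was 1.15 ± 0.45 and did not (limma adjusted p = 0.193). In matched libraries of control mice alone Mt1 was 4.31 and Hmox1 2.86. Lipid droplet genes were higher (median 0.43, adjusted p = 0.000589, adjusted p = 0.422 with an estimated correlation), led by the droplet protein gene Cidec (2.48 ± 0.58) and the fatty acid carrier gene Fabp4 (2.01 ± 0.45), the only members past the threshold of 15, with 3 adjusted over the list alone. In the fit to libraries with Y-linked reads of control and overexpressing mice they were -0.82 ± 0.66 (adjusted p = 0.552) and 0.82 ± 0.47 (adjusted p = 0.382). In matched libraries of control mice alone both stayed positive, with 2.13 for Fabp4 and a smaller rise than 2.48 for Cidec. The values of the joint fit can thus not be assigned to sex. Xenobiotic metabolism was higher (median 0.52, adjusted p = 0.000601, adjusted p = 0.586 with an estimated correlation), with Cyp2b10 and the sulfotransferase gene Sult1e1 (2.92 ± 0.48) past the threshold of 18 members, and 4 higher and 1 lower adjusted over the list alone. Genes of cholesterol synthesis and uptake were lower (median -0.79, adjusted p = 0.000118, adjusted p = 0.842 with an estimated correlation). Of its 20 members 3 fell over all genes, among them Insig1 (-2.67 ± 0.53), and 7 fell adjusted over the list alone. Fatty acid synthesis was lower (median -0.70, adjusted p = 0.0374) and inflammatory cytokines and chemokines were higher (median 0.25, adjusted p = 0.0365), both with an adjusted p = 0.842 with an estimated correlation. In the former Srebf1 fell among 19 members, with 3 falls adjusted over the list alone. In the latter Cxcl1 (2.92 ± 0.67) and Il1b (1.78 ± 0.40) rose among 16 members, with 3 rises adjusted over the list alone. Markers of sinusoidal endothelium went both ways, with Lyve1 (2.45 ± 0.48) and Pecam1 (0.78 ± 0.20) higher, Dnase1l3 (-0.87 ± 0.17) lower and an adjusted p of 0.485 for the list. Genes fixed for all comparisons did not pass the threshold here, with 0.17 ± 0.38 for Yap1, -0.32 ± 0.25 for Cyr61, -0.88 ± 0.42 for Ctgf, 0.37 ± 0.18 for Atf6, 0.00 ± 0.31 for the ER chaperone gene Hspa5 and 0.65 ± 0.70 for the stress factor gene Ddit3. The YAP target gene Ankrd1 had at most 0.426 CPM as a mean in any group and was not tested in any comparison.

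The number of ethanol calls in control mice fell with each library left out, and with a term for the sex chromosome genes. It was 23 with this term and 19 when pair-fed control replicates 2 and 3 were left out, which keeps 1 pair-fed control library that is assumed to vary like the other groups. Of the 23 named calls 5 and 4 were kept, among them Kcnk5, Slc34a2, Hsd3b2 and Etnppl in both. All 23 kept their sign, with the same values in both, such as 4.60 for Lcn2, 4.31 for Mt1, 3.31 for Fgf21 and 2.58 for Cyp2b10, and smaller changes such as -1.86 for A1bg. The count was 99 without pair-fed control replicate 2, 168 without pair-fed control replicate 3, 49 without ethanol-fed control replicate 2 and 180 without ethanol-fed control replicate 3. Of these 23 calls 9 (A1bg, Cyp2b10, Etnppl, Hmox1, Hsd3b2, Kcnk5, Nrep, Slc34a2 and Sult1e1) were kept whichever library was left out, and all 23 kept about 70% or more of their log2 change, such as Fgf21 (2.74 to 3.33). Fgf21 still lost its call with each of the 6 libraries left out. For genes chosen with groups that do not overlap, here and in the other comparisons, leaving out 1 library cannot turn the sign. Of the list calls, cholesterol synthesis was lost without pair-fed control replicate 2 (median -0.28), and xenobiotic metabolism without pair-fed control replicate 1 (median 0.39). Fatty acid synthesis was lost without pair-fed control replicate 2 (-0.08) or ethanol-fed control replicates 2 (-0.54) or 3 (-0.70), and with the term for the sex chromosome genes or matched libraries (-0.07 in both). The inflammatory list was lost without pair-fed control replicates 1 (0.31) or 2 (0.20) or ethanol-fed control replicate 1 (0.14). The barcode ranges were not balanced between these groups, and with them as a block the fatty acid (-0.68) and inflammatory (0.20) calls were lost.

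The comparison of knockout with control mice asked what the loss of Yap in hepatocytes changes on each diet. On the pair-fed diet Yap1 itself fell from 55.4 ± 4.8 to 8.50 ± 5.82 CPM (-2.74 ± 0.38, limma adjusted p = 0.00945), lower in 3 of 3 libraries, and no other gene passed the threshold. YAP target genes did not move as a list (22 members, median 0.09, adjusted p = 0.598), and values were -0.14 ± 0.25 for Cyr61 and -0.46 ± 0.42 for Ctgf. The values of the stress genes were 0.01 ± 0.18 for Atf6, -0.20 ± 0.31 for Hspa5 and 0.76 ± 0.70 for Ddit3. As lists, inflammatory cytokines and chemokines (median 0.44, adjusted p = 0.0085), fibrosis and stellate cell markers (median 0.27, adjusted p = 0.0308), lymphocyte markers (median 0.42, 9 of 9 members positive, adjusted p = 0.0413) and NRF2 targets (median 0.22, adjusted p = 0.0413) were higher in pair-fed knockout mice, with 0 members past the threshold over all genes or adjusted over the list alone in each of the 4 by limma. Each of the 4 had an adjusted p = 0.884 with an estimated correlation. Over all genes 367 had an unadjusted p under 0.05, fewer than the 586 expected by chance, and edgeR called 1 gene.

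All 3 pair-fed knockout libraries and 2 of the 3 pair-fed controls had Xist, and with matched libraries or with a term for the sex chromosome genes limma called 0 genes in the pair-fed comparison (Yap1 -2.67 in both, adjusted p = 0.0935 and 0.0918). In each case the inflammatory list (0.38) kept its call, the other 3 lost theirs, and 1 list not called before passed as lower. The matched libraries are those without pair-fed control replicate 1, and the term gives the same log2 changes, so these are not separate tests. The call of Yap1 was also lost without pair-fed control replicate 3 (-2.75) or knockout replicate 2 (-2.62) or 3 (-2.38). Limma called 2 genes without pair-fed control replicate 2. Without pair-fed knockout replicate 3 the inflammatory (0.44), fibrosis (0.27), lymphocyte (0.38) and NRF2 (0.37) calls were lost. The 3 lists lost in the matched fit, without pair-fed control replicate 1, had medians of 0.09 (fibrosis), 0.24 (lymphocyte) and 0.16 (NRF2). The lymphocyte call was also lost without knockout replicate 2 (0.26), and the NRF2 call without pair-fed control replicate 3 (0.17) or knockout replicate 1 (0.14).

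On the ethanol diet Yap1 fell from 62.4 ± 4.25 CPM in control to 4.39 ± 0.925 CPM in knockout mice (-3.57 ± 0.38, limma adjusted p = 0.000177). Hmox1 fell from 96.2, 183 and 350 CPM in the 3 control libraries to 32.9 ± 15.2 CPM (-2.54 ± 0.40, adjusted p = 0.0241). These were the only 2 genes past the threshold, each lower in 3 of 3 knockout libraries, and 978 genes had an unadjusted p under 0.05. Kupffer cell and macrophage markers were lower as a list in ethanol-fed knockout mice (13 of 15 members negative, median -0.62, camera adjusted p = 2.86e-08, adjusted p = 0.901 with an estimated correlation), with 0 members past the threshold over all genes by limma and 7 adjusted over the list alone. The values with the smallest adjusted p were -0.88 ± 0.24 for Cd5l, -0.87 ± 0.26 for Clec4f and -1.61 ± 0.47 for Marco (adjusted p = 0.34 each), all made by Kupffer cells. Markers of the other cell types of the sinusoid did not pass on this diet, with medians of 0.03 for endothelium (adjusted p = 0.951), 0.00 for lymphocytes (adjusted p = 0.736), -0.02 for stellate cells (adjusted p = 0.862) and -0.41 for neutrophils (adjusted p = 0.646, 4 of 5 negative). PERK-ATF4 targets were higher as a list (15 of 19 positive, median 0.78, adjusted p = 0.000233, adjusted p = 0.901 with an estimated correlation), with 4 members adjusted over the list alone. Ddit3, a member of that list, stood at 125.6, 153 and 6.71 CPM in the 3 ethanol-fed knockout libraries and at 10.9 ± 0.938 CPM in the controls (2.17 ± 0.70, adjusted p = 0.405). PPARA targets (median -0.18) and xenobiotic metabolism (median -0.55) were lower as lists, both with an adjusted p of 0.043 and an adjusted p = 0.974 with an estimated correlation, and 0 members of either passed over all genes or adjusted over the list alone. ATF6-dependent ER chaperones did not move (median 0.10). Values for the fixed genes were 0.58 ± 0.18 for Atf6, 0.15 ± 0.31 for Hspa5, -0.33 ± 0.25 for Cyr61 and -0.05 ± 0.42 for Ctgf, whose value was 0.05 without knockout replicate 3. YAP target genes had a median of -0.10 (adjusted p = 0.646).

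The ethanol-fed groups of this comparison were matched on sex chromosome genes, but the knockout virus was given at a lower dose than the control virus. The count of 2 genes rose to 9 without ethanol-fed control replicate 1 and to 36 without ethanol-fed knockout replicate 3. It was 1 without ethanol-fed control replicates 2 or 3 or knockout replicate 2, where Hmox1 was lost (-2.54, -2.07 and -2.32). The macrophage median was -0.39 without ethanol-fed control replicate 1, whose macrophage markers lay above those of its group. The PPARA and xenobiotic calls were lost without ethanol-fed control replicate 2 (-0.14 and -0.37), ethanol-fed control replicate 3 (-0.20 and -0.31) or knockout replicate 2 (-0.06 and -0.37).

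The comparison of overexpressing with control mice asked what added YAP changes. On the pair-fed diet the YAP target Cyr61 rose from 8.21 ± 0.723 to 23.5 ± 7.19 CPM (1.37 ± 0.25, limma adjusted p = 0.0279). It was the only one of 22 YAP target genes past the threshold (2 higher and 1 lower adjusted over the list alone, median 0.14, adjusted p = 0.0954), and Ctgf stood at 36.1 ± 14.4 against 20.9 ± 6.25 CPM (0.72 ± 0.42, adjusted p = 0.678). Yap1 itself did not pass (1.15 ± 0.38, adjusted p = 0.342), with replicate 1 at the level of the controls. The clock repressor gene Nr1d1 rose from 12.9 ± 1.91 to 74.2 ± 16.3 CPM (2.42 ± 0.37), and the lysosomal sulfatase gene Arsa rose by 1.76 ± 0.30 from 33.5 ± 20.1 CPM. Klhdc7a (1.57), Pik3ap1 (1.21) and Rassf3 (1.15) also rose. Falls were seen for the transcription factor gene Cux2, from 23.6 ± 18.7 to 0.061 ± 0.106 CPM (-4.24 ± 0.50), for the prolactin receptor gene Prlr (-1.72), for Fmo2 (-1.98), for Med12l (-2.32) and for BC089597 (-2.14). A1bg fell from 71.4 ± 91.9 CPM to no reads in 3 libraries. In all limma called 7 genes higher and 10 lower, with 991 at an unadjusted p under 0.05. edgeR called 29, with 15 of the 17 among them.

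By lists, cell cycle genes were higher in pair-fed overexpressing mice (20 of 20 positive, median 0.60, camera adjusted p = 4.15e-05, adjusted p = 0.543 with an estimated correlation), as were lipid droplet genes (14 of 15 positive, median 0.48, adjusted p = 1.88e-05, adjusted p = 0.394 with an estimated correlation). None of their members passed over all genes by limma, and 0 and 2 passed adjusted over the list alone. ATF6-dependent ER chaperones were higher (15 of 17 positive, median 0.32, adjusted p = 0.00659) and cholesterol synthesis was lower (19 of 20 negative, median -0.58, adjusted p = 0.00044), both with an adjusted p = 0.592 with an estimated correlation and 0 members past either threshold. Hspa5, Atf6 and Ddit3 had values of 0.46 ± 0.31, 0.49 ± 0.18 and 1.11 ± 0.70. PERK-ATF4 targets (median 0.34, adjusted p = 0.0136), inflammatory genes (median 0.43, adjusted p = 0.00527), interferon-stimulated genes (median 0.34, adjusted p = 0.00394) and NRF2 targets (median 0.21, adjusted p = 0.0451) were higher, each with an adjusted p = 0.543 with an estimated correlation. Of these only PERK-ATF4 targets had a member adjusted over the list alone, with 1. Xenobiotic metabolism was lower (median -0.16, adjusted p = 0.0485, adjusted p = 0.592 with an estimated correlation), with 4 falls adjusted over the list alone.

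Of the pair-fed libraries compared, the overexpression libraries all had Y-linked reads and 2 of the 3 controls did not, and with matched libraries or a term for the sex chromosome genes limma called 1 gene. None of the 12 named calls was kept, and all kept their sign, with 2.44 for Nr1d1, 1.26 for Cyr61 and 1.41 for Klhdc7a and smaller changes for Cux2 (-3.12), A1bg (-2.72), Arsa (0.87) and BC089597 (-0.90). Of the 9 list calls 7 were kept with matched libraries, where those of xenobiotic metabolism (-0.23) and NRF2 targets (0.30) were lost, and 6 with the term, where cholesterol synthesis (-0.35) was lost as well. With the barcode range as a block the xenobiotic call (-0.16) was lost. The count was 86 without pair-fed control replicate 1, 5 without pair-fed control replicate 2 or 3 or overexpression replicate 2, and 11 without overexpression replicate 3. With the 86, all controls left had Xist and all overexpression libraries Y-linked reads, so sex and YAP cannot be told apart there. A1bg, Cux2 and Prlr kept their calls whichever library was left out. These 3 genes and Fmo2 are known to be higher in female mouse liver, and 32 of 32 genes of a list known to differ with sex moved in the male direction here (median 1.24), so their calls cannot be assigned to YAP. Pair-fed overexpression replicate 2 stood apart, and without it the cell cycle (0.14), inflammatory (0.01), interferon (-0.01), NRF2 (0.08) and xenobiotic (-0.07) calls were lost. The cholesterol call was lost without pair-fed control replicate 2 (-0.07). Without pair-fed control replicate 1 the chaperone (0.23), PERK-ATF4 (0.28), inflammatory (0.24), interferon (0.13) and NRF2 (0.22) calls were lost. The chaperone call was also lost without pair-fed control replicate 3 (0.17) or overexpression replicate 1 (0.24), and without pair-fed control replicate 3 so were the NRF2 (0.28) and xenobiotic (-0.17) calls.

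On the ethanol diet, overexpressing mice had higher levels of genes for protein folding in the ER than control mice. The chaperone gene Hspa5 (BiP) rose from 667 ± 58.8 to 2360 ± 1520 CPM (1.65 ± 0.31, limma adjusted p = 0.0467) and the disulfide isomerase gene Pdia4 from 208 ± 22.0 to 656 ± 322 CPM (1.55 ± 0.24, adjusted p = 0.0153). Creld2 rose from 51.8 ± 13.0 to 443 ± 436 CPM (2.65 ± 0.46, adjusted p = 0.0336). Manf, which encodes a secreted factor of the ER, rose from 86.4 to 170 CPM in the control libraries to 573 ± 378 CPM (2.01 ± 0.38, adjusted p = 0.046). All 17 members of the list of ATF6-dependent ER chaperones and degradation genes were higher (median 1.13, camera adjusted p = 2.99e-24, adjusted p = 0.055 with an estimated correlation), with 4 past the threshold over all genes and 13 adjusted over the list alone. All 17 targets of the IRE1-XBP1 branch were higher too (median 0.64, adjusted p = 8.78e-14, adjusted p = 0.0835 with an estimated correlation), with Pdia5 (1.10 ± 0.20) past the threshold and 12 adjusted over the list alone. The remaining branch went the other way, as 17 of 19 PERK-ATF4 targets were lower (median -0.47, adjusted p = 0.0108, adjusted p = 0.786 with an estimated correlation), with 0 members past either threshold by limma. Atf6 (0.19 ± 0.18) and Ddit3 (0.61 ± 0.70) did not pass. The cytosolic chaperone gene Hsph1 (1.81 ± 0.24, adjusted p = 0.00406) and Magt1 (1.27 ± 0.23) also rose, and Gpcpd1 (-2.21 ± 0.35), Fam134b, a receptor for degradation of the ER (-2.10 ± 0.35), and the ceramidase gene Acer2 (-1.32 ± 0.25) fell.

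**Figure D2:**
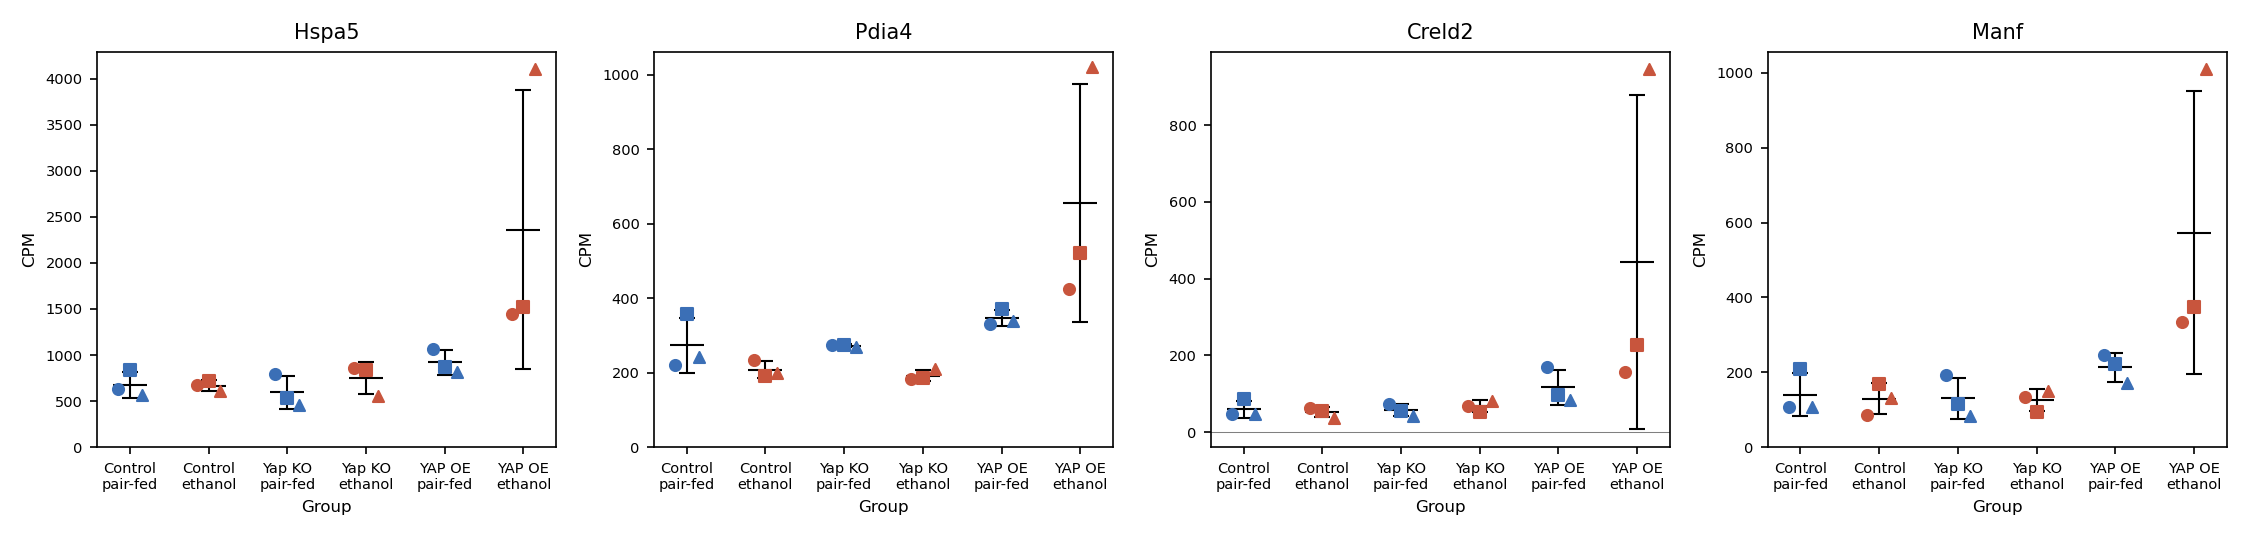
Levels of Hspa5, Pdia4, Creld2 and Manf in CPM (y axis) in the 6 groups (x axis), with 1 point per library (circle, square and triangle for replicates 1, 2 and 3; blue for pair-fed, red for ethanol-fed) and bars for the mean ± SD of 3 libraries. The 3 ethanol-fed overexpression libraries had 1450, 1520 and 4110 CPM of Hspa5, all above the ethanol-fed controls at 605 to 722 CPM.

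Other lists moved less in ethanol-fed overexpressing mice. Acute phase genes (median 0.40, 18 of 21 positive, adjusted p = 0.00394) and interferon-stimulated genes (median 0.25, adjusted p = 0.00266) were higher, and fatty acid synthesis (median -0.42, adjusted p = 0.0114) and PPARA targets (median -0.26, adjusted p = 0.00744) were lower, each with an adjusted p = 0.786 with an estimated correlation. No member of these 4 lists passed over all genes by limma, and 0, 3, 2 and 1 passed adjusted over the list alone. Yap1 stood at 122 ± 19.5 against 62.4 ± 4.25 CPM, higher in 3 of 3 libraries without passing the threshold (0.94 ± 0.38, adjusted p = 0.449). YAP target genes did not move as a list (median 0.03, adjusted p = 0.583), with 0.52 ± 0.25 for Cyr61 and -0.37 ± 0.42 for Ctgf, whose sign turned without ethanol-fed overexpression replicate 2. Limma called 8 genes higher and 4 lower (1036 at an unadjusted p under 0.05), and edgeR called 14.

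Of the 12 calls 0 were left by limma without ethanol-fed control replicate 2 or ethanol-fed overexpression replicate 3 and 5 without ethanol-fed control replicate 1. No named call was kept whichever library was left out, with fewer libraries in the test. The 10 named calls all kept their sign and about 70% or more of their log2 change, as for Hsph1 (1.58 to 2.07), Pdia4 (1.18 to 1.81), Gpcpd1 (-2.47 to -1.87) and Hspa5 (1.15 to 1.91). The count was 4 with quantile normalization or a replicate block, 2 with the barcode range as a block and 1 with no filter. The 2 lists of ER genes kept their calls without each library, with medians from 0.85 to 1.39 for ATF6-dependent genes and from 0.42 to 0.77 for IRE1-XBP1 targets. The acute phase call was lost without ethanol-fed control replicate 3 (0.24) or overexpression replicate 2 (0.20) or 3 (0.25), and the interferon call without overexpression replicate 2 (0.25). The fatty acid call was lost without control replicate 1 (-0.12) or overexpression replicate 2 (-0.29) or 3 (-0.32). The PPARA call was lost without control replicate 2 (-0.19) or overexpression replicate 2 (-0.24) or 3 (-0.09). The PERK-ATF4 call was lost without control replicate 2 (-0.39) or 3 (-0.42) or overexpression replicate 2 (-0.39).

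In knockout mice ethanol-fed and pair-fed libraries differed more than in the other genotypes, and they also differed in their sex chromosome genes, so diet and sex cannot be told apart there. Eif2s3y and Uty stood at 57.8 ± 9.94 and 43.2 ± 7.96 CPM and Ddx3y at 78.6 to 128.8 CPM in the ethanol-fed knockout libraries, and all 3 had no reads in the pair-fed ones. Xist fell from 374 ± 23.0 to 1.22 ± 1.32 CPM. A1bg, known to be higher in the liver of female mice, fell from 132 ± 68.7 to 0.736 ± 0.323 CPM. Sult2a2 (306 ± 87.4 to 0.793 ± 1.22 CPM), Sult2a1 (82.4 ± 23.8 to 0.303 ± 0.277 CPM) and Cyp2c69 (1130 ± 587 to 12.2 ± 10.6 CPM) fell as well. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 8.73 ± 4.45 to 355 ± 18 CPM (5.29 ± 0.57, limma adjusted p = 3.87e-05). Cyp2b10 rose from 18.3 ± 3.81 to 577 ± 90.4 CPM (4.91 ± 0.48, adjusted p = 2.27e-05) and Lcn2 from 12.9 ± 8.27 to 635 ± 336 CPM (5.48 ± 0.86, adjusted p = 0.000836). Limma called 481 genes higher and 679 lower, with 3058 at an unadjusted p under 0.05. With TMM factors 673 were higher and 577 lower, so the balance of directions depended on the scaling.

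Macrophage markers fell in ethanol-fed against pair-fed knockout mice (14 of 15 negative, median -1.34, camera adjusted p = 5.86e-07, adjusted p = 0.582 with an estimated correlation), with 10 past the threshold over all genes and 11 adjusted over the list alone. Among them were the complement receptor gene Vsig4 (82.9 ± 14.4 to 24.7 ± 1.5 CPM, -1.70 ± 0.24), the receptor gene Csf1r (-1.72 ± 0.29), Cd5l (-1.36 ± 0.24) and the Kupffer cell lectin gene Clec4f (-1.34 ± 0.26). Lymphocyte markers were lower (median -0.73, adjusted p = 0.0285, adjusted p = 0.734 with an estimated correlation), and 2 of 9 fell by both counts. PERK-ATF4 targets rose (median 1.07, adjusted p = 2.50e-06, adjusted p = 0.582 with an estimated correlation), with 8 of 19 past the threshold over all genes and 10 adjusted over the list alone. Among these were the transcription factor gene Atf3 (3.93 ± 0.76), Trib3 (3.6 ± 0.60) and the amino acid synthesis genes Asns (3.01 ± 0.57) and Psat1 (2.46 ± 0.58), while Ddit3 did not pass (2.06 ± 0.70, adjusted p = 0.0669). Acute phase genes rose (median 0.80, adjusted p = 1.13e-05, adjusted p = 0.582 with an estimated correlation), with 6 higher and 1 lower over all genes, and 12 higher and 1 lower adjusted over the list alone. Serpina3n (1.93 ± 0.39) and Steap4 (1.81 ± 0.27) rose, and Crp (-0.86 ± 0.18) fell. Cholesterol synthesis fell (median -0.95, adjusted p = 8.99e-05, adjusted p = 0.813 with an estimated correlation), with 6 of 20 past the threshold over all genes and 7 adjusted over the list alone, as for Insig1 (-2.83 ± 0.53) and Mvd (-2.66 ± 0.70). PPARA targets fell (median -0.44, adjusted p = 0.000575, adjusted p = 0.734 with an estimated correlation), with 6 of 22 over all genes and 8 adjusted over the list alone, among them Acot3 (-3.54 ± 0.46), Ehhadh (-1.19 ± 0.19) and Ppara itself (-1.17 ± 0.24). Fatty acid synthesis was lower (median -0.88, adjusted p = 0.0236, adjusted p = 0.895 with an estimated correlation; 1 rise and 3 falls over all genes, 1 and 5 adjusted over the list alone). Lipid droplet genes were higher (median 0.37, adjusted p = 0.026, adjusted p = 0.734 with an estimated correlation; 3 rises and 1 fall over all genes, 4 and 1 adjusted over the list alone).

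Lists that did not pass as a whole still held calls in ethanol-fed knockout mice. Among the 22 YAP target genes 1 rose and 5 fell over all genes, and 2 rose and 6 fell adjusted over the list alone (median -0.43, adjusted p = 0.104). Values were 2.13 ± 0.53 for Gadd45a, -1.67 ± 0.38 for Axl, -1.26 ± 0.27 for Amotl2 and -0.94 ± 0.18 for Wwc1. In the circadian clock list Per3 (-2.02 ± 0.42) and Dbp (-1.96 ± 0.45) fell and Clock (1.00 ± 0.25) and Nfil3 (1.21 ± 0.34) rose. Among periportal hepatocyte genes Uroc1 (-0.79 ± 0.16) and Ctsc (-0.98 ± 0.25) fell and Sdsl (1.10 ± 0.25) and Asl (0.92 ± 0.24) rose. Atf6 rose from 93.1 ± 5.18 to 180 ± 13.0 CPM (0.94 ± 0.18, adjusted p = 0.00277), while Hspa5 (0.35 ± 0.31), Cyr61 (-0.51 ± 0.25), Ctgf (-0.48 ± 0.42) and Yap1 (-0.66 ± 0.38) did not pass. With a term for the sex chromosome genes limma called 0 genes and no named call was kept. Some values stayed near their size under it, such as Cdkn1a (4.88), Lcn2 (5.52), Trib3 (3.36) and Acot3 (-3.29). Others shrank, such as Sult2a1 (-0.93), Asl (0.25) and Ctsc (-0.1), and among the named calls only Cyp2c69, Sult2a2, Xist and Clock turned sign. A call lost under this term does not show that sex explains it. Of the 8 list calls 6 were kept, and those of fatty acid synthesis (1.15) and lymphocytes (-0.01) were lost. With this term the separation of diet from sex rests on the pair-fed control group alone, the only one with both kinds of library. The count was 621 without pair-fed knockout replicate 2, 628 without ethanol-fed knockout replicate 1 and 623 without ethanol-fed knockout replicate 2. Of the 41 named calls 32 were kept whichever library was left out. All 41 kept their sign and about 67% or more of their log2 change, the least being Mvd (-3.16 to -1.77). The fatty acid and lipid droplet calls were lost without pair-fed knockout replicate 1 (-0.05 and 0.45) or ethanol-fed knockout replicate 3 (-0.46 and 0.49). The lymphocyte call was lost without pair-fed replicate 3 (-0.70) or ethanol-fed replicates 1 (-0.68) or 2 (-0.76).

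In overexpressing mice, whose libraries were matched on sex chromosome genes, ethanol raised Cyp2b genes and acute phase genes. Cyp2b13 rose from 0.911 ± 0.803 to 79.1 ± 31.6 CPM (5.42 ± 1.22) and Cyp2b9 from 14.1 ± 7.96 to 373 ± 48.6 CPM (4.76 ± 0.73, limma adjusted p = 0.00367). Cyp2b10 rose from 27.1 ± 10.9 to 334 ± 52.0 CPM (3.63 ± 0.48, adjusted p = 0.0012) and Lcn2 from 37.7 ± 46.1 to 854 ± 602 CPM (4.81 ± 0.86). Fgl1, which encodes a liver-secreted fibrinogen-like protein, rose from 95.5 to 159 CPM in the pair-fed libraries to 1040 ± 821 CPM (2.75 ± 0.45), and Slc34a2 also rose (3.30 ± 0.50). The endothelial lipase gene Lipg fell from 140 ± 38.4 to 20.2 ± 9.62 CPM (-2.79 ± 0.31, adjusted p = 0.000251), the uridine phosphorylase gene Upp2 from 541 ± 218 to 45.8 ± 13.1 CPM (-3.50 ± 0.56) and Hsd3b5 from 35.9 ± 31.9 to 0.238 ± 0.277 CPM (-3.98 ± 0.75). YAP targets Ctgf (36.1 ± 14.4 to 9.59 ± 7.43 CPM, -1.97 ± 0.42), Cyr61 (23.5 ± 7.19 to 9.60 ± 0.372 CPM, -1.16 ± 0.25) and Amotl2 (-1.25 ± 0.27) fell and Nuak2 (0.88 ± 0.21) rose. Their list did not pass (median -0.25, adjusted p = 0.065), with 2 rises and 7 falls adjusted over the list alone, and Yap1 stayed at -0.04 ± 0.38. In all limma called 47 genes higher and 88 lower (1704 at an unadjusted p under 0.05), and with TMM factors 77 higher and 50 lower.

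The acute phase list was the only one in the comparisons whose call was kept with an estimated correlation (20 of 21 positive, median 1.2, camera adjusted p = 7.86e-20, adjusted p = 0.0455 with an estimated correlation). Of its genes 6 were past the threshold over all genes and 17 adjusted over the list alone, such as Serpina3n (1.95 ± 0.39), Orm1 (1.67 ± 0.31) and Itih4 (1.2 ± 0.25). ATF6-dependent ER genes rose in ethanol-fed against pair-fed overexpressing mice (16 of 17 positive, median 0.86, adjusted p = 1.74e-11) and so did IRE1-XBP1 targets (16 of 17 positive, median 0.51, adjusted p = 3.78e-09), both with an adjusted p = 0.195 with an estimated correlation. Over all genes 2 and 1 members passed, the chaperone gene Hsp90b1 (1.23 ± 0.26), Xbp1 (0.86 ± 0.15) and Pdia5, and 12 and 7 adjusted over the list alone. Hspa5 (1.19 ± 0.31, adjusted p = 0.0658), Atf6 (0.07 ± 0.18) and Ddit3 (0.15 ± 0.70) did not pass. Xenobiotic metabolism rose (median 0.72, adjusted p = 1.59e-05, adjusted p = 0.234 with an estimated correlation; 3 rises and 1 fall, 5 and 1 adjusted over the list alone) although the receptor gene Nr1i2 fell (-0.89 ± 0.20). Neutrophil markers were higher (5 of 5 positive, median 1.04, adjusted p = 0.00153, adjusted p = 0.234 with an estimated correlation; 0 members past the threshold by limma, 2 adjusted over the list alone). Gluconeogenesis and glycolysis genes were lower (median -0.58, adjusted p = 0.00189, adjusted p = 0.234 with an estimated correlation; 2 falls by both counts), with Pfkfb3 (-2.48 ± 0.43) and Txnip (-1.55 ± 0.37) past the threshold. Fatty acid synthesis fell (median -0.97, adjusted p = 0.000185, adjusted p = 0.441 with an estimated correlation; 3 falls, 5 adjusted over the list alone), with the desaturase genes Fads2 (-1.43 ± 0.27) and Fads1 (-1.14 ± 0.21) and with Lpin1 (-2.49 ± 0.54). PPARA targets (median -0.38, adjusted p = 0.000452, adjusted p = 0.441 with an estimated correlation; 1 fall, 2 rises and 9 falls adjusted over the list alone) and genes of ethanol and acetaldehyde metabolism (median -0.32, adjusted p = 0.0356, adjusted p = 0.441 with an estimated correlation; 2 falls, 3 adjusted over the list alone) were lower, the latter with Adh4 (-1.11 ± 0.26) and Aldh3a2 (-1.17 ± 0.26). Cell cycle genes were lower (18 of 20 negative, median -0.51, adjusted p = 0.00269, adjusted p = 0.498 with an estimated correlation; 0 past the threshold by limma, 2 adjusted over the list alone). The clock genes Nr1d1 (-2.05 ± 0.37) and Dbp (-2.33 ± 0.45) fell in a list that did not pass (adjusted p = 0.657).

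The count of 135 ethanol calls in overexpressing mice was 34 without pair-fed overexpression replicate 1, 27 without pair-fed replicate 3, 17 without ethanol-fed overexpression replicate 2, 33 without ethanol-fed replicate 3 and 57 with no filter. Of the 28 named calls 6 were kept whichever library was left out (Cyp2b10, Cyp2b9, Fgl1, Lipg, Slc34a2 and Upp2). All 28 kept their sign and about 63% or more of their log2 change, such as Cyp2b13 (5.00 to 5.74), Adh4 (-1.20 to -0.97) and Hsp90b1 (0.78 to 1.54). Cyp2b13 and Adh4 still lost their calls with each of the 6 libraries left out. The cell cycle call was lost without pair-fed overexpression replicate 2 (-0.12), and the ethanol metabolism call without pair-fed replicate 3 (-0.44) or ethanol-fed replicate 3 (-0.45).

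**Figure D3:**
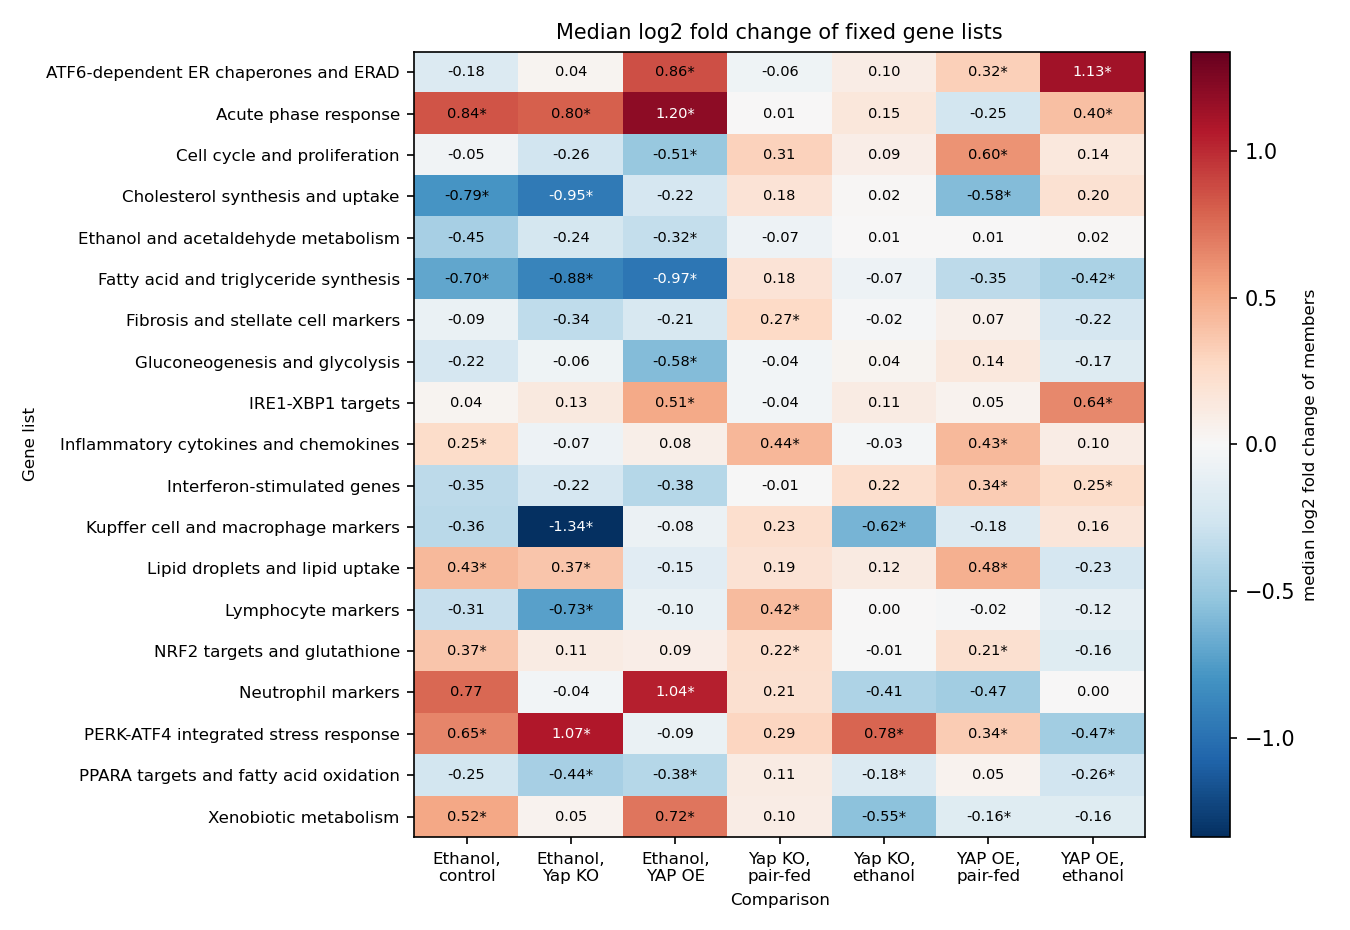
Median log2 fold change of the members of each gene list called in at least 1 of the 7 comparisons of 2 groups (colour and number; lists on the y axis, comparisons on the x axis; KO, knockout; OE, overexpression), with an asterisk where the camera adjusted p with its preset correlation was under 0.05. ATF6-dependent ER genes had their highest median, 1.13, in ethanol-fed overexpressing mice, and macrophage markers their lowest, -1.34, in the ethanol response of knockout mice, whose diets differed in sex chromosome genes.

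The ethanol responses of control and overexpressing mice, which share no library, overlapped. Of the 120 and 47 genes higher with ethanol 13 were shared where 0.48 would be expected, and of the 196 and 88 lower genes 26 were shared where 1.47 would be expected. There were 0 called in opposite directions by limma. All the responses take the spread of a gene from the same fit to 18 libraries. Genes of small spread can thus pass more easily in 2 responses, and the expected counts leave this out. Of the 316 calls in control mice 267 had the same sign in overexpressing mice. Control and knockout mice shared 76 of their higher and 116 of their lower genes (4.92 and 11.36 expected). Both comparisons set ethanol-fed libraries with Y-linked reads against pair-fed groups with Xist in 2 and in 3 of 3 libraries, so a difference in sex can add to this overlap, which was not tested, and the expected counts leave it out. Knockout and overexpressing mice shared 23 and 31 (1.93 and 5.1 expected), with 5 genes called in opposite directions.

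Whether the ethanol response differed between genotypes was tested by interaction. No single gene passed in knockout against control mice (limma, 666 at an unadjusted p under 0.05, smallest adjusted p = 0.662, 0 by edgeR) or in overexpressing against control mice (847, smallest adjusted p = 0.0907, 0 by edgeR). Differences between genotypes in which single genes responded to ethanol are thus not established. In overexpressing mice this holds for the ER chaperone gene Hspa5 (1.19 ± 0.44, adjusted p = 0.538) as for Atf6 (-0.30 ± 0.25) and Ddit3 (-0.50 ± 0.99). In knockout mice these interaction values were 0.35 ± 0.44 for Hspa5, 0.57 ± 0.25 for Atf6 and 1.41 ± 0.99 for Ddit3. The interactions of Yap1, Cyr61 and Ctgf did not pass either, with -0.83 ± 0.54, -0.19 ± 0.36 and 0.41 ± 0.60 in knockout mice and -0.21 ± 0.54, -0.84 ± 0.36 and -1.09 ± 0.60 in overexpressing mice. Up to 3 genes passed in knockout mice without a single library (1 without ethanol-fed control replicate 1 or pair-fed knockout replicate 3, 3 without ethanol-fed knockout replicate 3). In overexpressing mice 27 passed without pair-fed control replicate 1, 2 without pair-fed overexpression replicate 2 and 1 without pair-fed overexpression replicate 3. Replicate 1 is the only pair-fed control with Y-linked reads. Without it the pair-fed controls had Xist alone, so a difference in sex cannot be told apart from the interaction for these 27. As lists, ATF6-dependent ER genes responded more to ethanol in overexpressing than in control mice (15 of 17 positive, median 1.10, camera adjusted p = 8.03e-09, adjusted p = 0.407 with an estimated correlation), with 0 members past the threshold over all genes by limma and 11 adjusted over the list alone. Macrophage markers responded with lower values in knockout than in control mice (13 of 15 negative, median -0.80, adjusted p = 5.22e-08, adjusted p = 0.919 with an estimated correlation), with 0 over all genes and 7 adjusted over the list alone. This interaction includes the pair-fed groups that differ in sex chromosome genes, and that of overexpressing mice includes the same pair-fed controls. Without pair-fed control replicate 1, which matches the pair-fed groups of the knockout interaction, its 3 list calls were kept.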

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

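Except for the splits of the libraries, all the tests of explanations in this part, and the term for the sex chromosome genes, were chosen after the results they concern had been seen.

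The calls of the ethanol response in knockout mice (1160 genes) set ethanol-fed libraries with Y-linked reads against pair-fed libraries with Xist. A list of 32 genes known to differ between male and female mouse liver had a median in the male direction of 1.42 (95% interval 0.84 to 2.73, 28 of 32 genes), 1.24 in pair-fed overexpression, -1.17 in pair-fed knockout and -0.19 with ethanol in control mice. In comparisons of matched libraries it was -0.94 (-1.25 to -0.59, ethanol in overexpressing mice), 0.44 (0.21 to 0.8, ethanol-fed overexpression) and 0.35 (0.04 to 0.95, ethanol-fed knockout). The intervals of this list were resampled over genes. The list thus also moved without a difference in sex chromosome genes and does not measure sex alone. The 1.42 runs the way a difference in sex would for these genes, opposite to ethanol in matched overexpressing mice. Sex as the cause of all the calls is argued against by the overexpressing mice. There the same calls, turned to their direction in knockout mice, had a median of 0.29 (1.09 in knockout mice), and 887 of 1160 (76.5%) had the same sign. The interval of that median (0.27 to 0.32) was resampled over genes, which share the same libraries, so it leaves out the spread between libraries. Apart from the genes of the sex chromosomes, diet and sex stay open for any single gene within this genotype, as no library separates them there. A response to ethanol that differs with Yap was not tested apart from them.

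The higher ER chaperone genes of ethanol-fed overexpressing mice (median 1.13 over 17 genes) included 1 library, replicate 3, with 4110 CPM of Hspa5. Without it the median of the list was 0.85 and its call was kept, although no single gene was called by limma without it, so that library alone does not account for the list. With the barcode range as a block the median was 1.16, which argues against it as the cause. A response of ER folding genes to the YAP virus under ethanol may be the source, as a hypothesis from the data it was found in, with adjusted p = 0.055 with an estimated correlation. Load from the viral protein itself, YAP with EGFP against GFP, was not tested and stays open.

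The lower macrophage markers of ethanol-fed knockout mice (median -0.62, 95% interval -0.80 to -0.14 over genes) could reflect a lower share of all cells other than hepatocytes in the tissue taken. Endothelial and stellate markers had medians of 0.03 (-0.20 to 0.29) and -0.02 (-0.08 to 0.18), but the interval of the endothelial markers overlapped that of the macrophage markers. Although the gap to both resampled over genes excluded 0 (-0.65, -1.03 to -0.26, and -0.60, -0.94 to -0.28), it treats genes as independent and was chosen after the first test had left the question open. Per library the gap to endothelial markers overlapped between ethanol-fed control (-0.18, -1.14 and -0.94) and knockout (-1.36, -1.51 and -1.11), while the gap to stellate markers did not (0.98, -0.01 and -0.17 against -0.19, -0.30 and -0.50), so this explanation is left open. The barcode range is argued against (median -0.58 with it as a block), while the lower virus dose of the knockout arm cannot be told apart from the knockout, since they go together in each library, and the list median in pair-fed knockout mice was 0.23.

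Lists whose response to ethanol differed between genotypes by a test of the interaction (camera, limma, Benjamini-Hochberg) were the following, none of them called with an estimated correlation. In knockout against control mice these were macrophage markers (-0.80), PPARA targets (-0.16, adjusted p = 0.0102, adjusted p = 0.919 with an estimated correlation) and xenobiotic metabolism (-0.52, adjusted p = 0.038, adjusted p = 0.919 with an estimated correlation). The PPARA call was lost without pair-fed control replicate 2 (-0.09), ethanol-fed control replicate 2 (-0.13), pair-fed knockout replicates 2 (-0.08) and 3 (-0.11) or ethanol-fed knockout replicate 2 (-0.09), and the xenobiotic call without ethanol-fed control replicates 2 (-0.32) and 3 (-0.28), pair-fed knockout replicates 2 (-0.56) and 3 (-0.46) or ethanol-fed knockout replicate 2 (-0.42). In overexpressing against control mice the medians were 1.10 for ATF6-dependent ER genes, 0.50 for IRE1-XBP1 targets (adjusted p = 7.67e-06), -0.77 for PERK-ATF4 targets (adjusted p = 6.37e-05), -0.58 for lipid droplet genes (adjusted p = 7.67e-06), 0.72 for cholesterol synthesis (adjusted p = 0.0019), 0.61 for acute phase genes (adjusted p = 0.0036), -0.55 for cell cycle genes (adjusted p = 0.000721), -0.56 for NRF2 targets (adjusted p = 0.00908), -0.36 for inflammatory genes (adjusted p = 0.0116) and -0.19 for gluconeogenesis (adjusted p = 0.0152). With an estimated correlation the adjusted p of the first 3 was 0.407, that of lipid droplet genes 0.397, that of cholesterol synthesis 0.679 and that of the other 5 lists 0.469. The cell cycle call was lost without pair-fed overexpression replicate 2 (-0.13), and the cholesterol call without pair-fed control replicate 2 (0.05) or ethanol-fed overexpression replicate 1 (0.43). The cholesterol call was also lost with a term for the sex chromosome genes or matched libraries (0.45 in both), and the inflammatory call with the barcode range as a block (-0.20). Without single libraries the calls of acute phase, NRF2, inflammatory and gluconeogenesis genes were also lost, with medians ranging from 0.30 to 0.84, -0.75 to -0.36, -0.76 to -0.21 and -0.53 to -0.07, and the calls of ER genes of both branches, PERK-ATF4 targets and lipid droplet genes were kept whichever library was left out.

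For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 316 and 18 genes for ethanol in control mice, 1160 and 40 in knockout mice and 135 and 0 in overexpressing mice, 17 and 0 for pair-fed and 12 and 1 for ethanol-fed overexpression, 1 and 308 for pair-fed knockout and 2 and 31 for ethanol-fed knockout. The real split was the only one with as many genes in the first 5 of these, while 3 of 10 and 2 of 10 splits had as many in the last pair. The split with 308 genes set pair-fed control replicate 3 and knockout replicates 2 and 3 against the rest, which points to a structure among these libraries other than genotype. For lists the real counts, the highest others and the splits with as many were 8, 8 and 3 (ethanol in control), 8, 7 and 1 (in knockout), 10, 17 and 5 (in overexpression), 4, 6 and 7 (pair-fed knockout), 4, 8 and 9 (ethanol-fed knockout), 9, 12 and 5 (pair-fed overexpression) and 7, 16 and 4 (ethanol-fed overexpression). For the interactions 100 splits were drawn. They do not test the genes, since the real counts were 0 by limma (666 and 847 genes at an unadjusted p under 0.05, and 0 by edgeR) and any split has as many; other splits had up to 368 and 5. The lists had 3 and 10 real calls, with up to 11 and 17 in other splits and as many in 73 and 25 of the splits, so chance was not excluded for them. The 368 genes, with ethanol-fed control replicate 1 and ethanol-fed knockout replicates 1 and 2 in 1 group, point to a structure among those libraries.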

How the results depend on the processing

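The term for the sex chromosome genes and the comparisons matched on them were chosen after the data had been seen; the other alternatives were planned. Calls are limma counts; the cause of a change was not tested unless stated.

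With array weights the counts were 537 (ethanol in control), 2235 (in knockout), 505 (in overexpression), about 1.1e2 (ethanol-fed knockout, 78 higher and 27 lower), 33 and 71 (pair-fed and ethanol-fed overexpression) and 9 (overexpression interaction). Fitting only the libraries compared, with fewer degrees of freedom, gave 140, 753, 267, 4 and 5 for ethanol in control, knockout and overexpression, ethanol-fed knockout and pair-fed overexpression, 0 for pair-fed knockout and 2 for the overexpression interaction. A term for the sex chromosome genes gave 23 (ethanol in control), 0 (in knockout, where sex and diet coincide), 0 (pair-fed knockout), 1 (pair-fed overexpression) and 1 (overexpression interaction), and matched libraries, fewer in number, gave 19, 0, 1 and 1 where they could be formed. Lists were then 2 for pair-fed knockout with either, and 14 for pair-fed overexpression with matched libraries. No filter gave 57 (ethanol in overexpression), 2 (pair-fed knockout), 1 (ethanol-fed overexpression) and 1 (overexpression interaction). edgeR gave 29 (pair-fed overexpression), a pseudocount of 10 gave 0 (pair-fed knockout), and quantile normalization 4 (ethanol-fed overexpression) and 2 lists (ethanol-fed knockout). The barcode block gave 1 and 2, and the replicate block 1 and 4, for ethanol-fed knockout and overexpression. A filter of 10 CPM left 2 lists (pair-fed knockout). An estimated correlation left 0 lists in each contrast but 1 in the ethanol response of overexpressing mice.

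Leaving out 1 library gave 49 to 281 (ethanol in control), 621 to 1209 (in knockout), 17 to 149 (in overexpression), 0 to 2 and 1 to 36 (pair-fed and ethanol-fed knockout), 5 to 86 and 0 to 10 (pair-fed and ethanol-fed overexpression), and 0 to 3 and 0 to 27 (interactions). Lists were 5 to 9, 6 to 8, 10 to 13, 1 to 6, 2 to 5, 5 to 14, 2 to 11, 1 to 8 and 8 to 14 in the same order.

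Signs turned mostly for values near 0. The fatty acid list with ethanol in control (median -0.70) was -0.07 with the sex term and -0.07 with matched libraries, where the direction of its test turned while the median stayed negative. Hspa5 with ethanol in control (0.00) was 0.02 with the barcode block, 0.03 (quantile), 0.09 (TMM), 0.08 (edgeR, sex term, matched) and 0.05 (array weights), and -0.12 to 0.16 without single libraries. Atf6 in pair-fed knockout (0.01) was -0.01 (TMM) and -0.02 (edgeR), and -0.14 to 0.12 without single libraries. Ctgf in ethanol-fed knockout (-0.05) was 0.09 with array weights and -0.16 to 0.05 without single libraries, and in ethanol-fed overexpression -0.91 to 0.13. With ethanol in overexpression Yap1 (-0.04) was 0.01 (quantile) and 0.05 (TMM), and without single libraries -0.59 to 0.35, Ddit3 -0.09 to 0.52 and Atf6 -0.04 to 0.20; the interaction of Yap1 was -0.76 to 0.18. The sex term takes its sex difference from the pair-fed control group alone. In the ethanol response of knockout mice it turned called values far from 0: Cyp2c69 (-6.60) was 1.65, Sult2a2 (-7.59) 0.08, Xist (-7.55) 0.65, Clock (1.00) -0.08 and the fatty acid list (-0.88) 1.15. The other named calls kept their sign. Some stayed near their size, such as Cdkn1a (4.88) and Lcn2 (5.52), and others shrank, such as Sult2a1 (-0.93) and Acadl (-0.39).

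The interaction of ethanol with knockout had 0 genes under each alternative but leaving out 1 library (limma; 0 by edgeR, 666 at an unadjusted p under 0.05). DESeq2 size factors and edgeR without TMM, planned only for main values that are counts, were not run on the recovered reads; for CPM the plan named quantile normalization and TMM factors. Numbers do not pair the libraries: residuals of the same number had a median correlation across genes of 0.03, those of different numbers -0.01. At 4.68 to 5.81 M reads, values under 0.517 to 0.641 CPM are within the limit that 0 reads allow.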

Other observations

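All the tests reported here were chosen after the results had been seen, and the list of heat shock genes was written after the files were read.

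Protein folding genes outside the ER were also higher in ethanol-fed overexpressing than in ethanol-fed control mice. Of 15 heat shock genes, most of them cytosolic, 13 were positive (median 0.52, camera p = 5.07e-10, p = 0.00469 with an estimated correlation), with Hsph1 past the threshold over all genes and 6 adjusted over the list alone. The co-chaperone genes Stip1 (68.2 ± 10.5 to 182 ± 38.9 CPM, 1.39 ± 0.30, limma adjusted p = 0.082), Chordc1 (33.4 ± 0.651 to 67.5 ± 13.9 CPM, 0.98 ± 0.19, adjusted p = 0.0589) and Ahsa2 (0.78 ± 0.18, adjusted p = 0.114) did not pass over all genes. The list was written after Hsph1 had been seen among the calls of this comparison and includes it, so these values describe the pattern and do not test it. In control mice the same list was lower with ethanol (median -0.57, 8 members adjusted over the list alone, camera p = 0.00305, p = 0.125 with an estimated correlation), and in overexpressing mice it had a median of 0.06 with ethanol (p = 0.233).

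The ethanol calls of control mice could depend on pair-fed controls with Xist. In a fit to the 10 libraries with Y-linked reads of control and overexpressing mice (4 pair-fed, 6 ethanol-fed), 226 of the 316 calls (71.5%) had the same direction with an unadjusted p under 0.05, with a median of 0.69, and limma called 332 genes, 217 of them lower, of which 99 were shared. Of the 23 named calls of control mice 21 kept their sign there and 10 were past the threshold. These 10 were Lcn2 (4.74 ± 0.76), Slc34a2 (3.46 ± 0.26), Mt1 (3.45 ± 0.30), Cyp2b10 (3.28 ± 0.41), Orm3 (2.74 ± 0.53), Kcnk5 (-2.31 ± 0.26), Hsd3b2 (-2.24 ± 0.37), Etnppl (-2.07 ± 0.41), Nrep (-1.75 ± 0.38) and Dnase1l3 (-0.65 ± 0.14). The other 13 did not pass, with the same sign for Cxcl1 (2.00), Sult1e1 (1.66), Insig1 (-1.47), Fgf21 (1.39), Lyve1 (1.21), Hmox1 (1.15), Il1b (0.98), Fabp4 (0.82), Gdf15 (0.78), Steap4 (0.39) and Pecam1 (0.37) and the opposite sign for A1bg (0.15) and Cidec (-0.82). This fit shares the ethanol-fed control libraries and pair-fed control replicate 1 with the comparison it tests, so it is not independent of it. It has a common ethanol term for both genotypes, and most of its pair-fed libraries are from overexpressing mice. Genotype is thus mixed with sex, and the fit cannot decide whether the calls depend on controls with Xist. In matched libraries of control mice alone all 23 named calls kept their sign, A1bg (-1.86) and Cidec among them.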
